A study of Homo sapiens with 6 samples.

How the data were processed

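Polyadenylated RNA of HEK293 cells, an established human line from embryonic kidney, was measured by sequencing after treatment with the compound B23 or with the solvent DMSO. Each group held 3 libraries, and the treatment label of each sample gave its group. Libraries were made with a strand-preserving mRNA kit, per the labels' protocols. STAR 2.6.1d, SAMtools, HTSeq and edgeR are named with the build hg38 in the submitters' processing notes, which give no order or settings for them. The annotation, the strand setting of the counting, the filter on listed genes, the dose and the treatment time are not given in the sources used here.

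The deposited table holds CPM, read counts scaled to a common library size, for 15496 gene symbols in 6 columns, 1 per library, per the labels and the values. The values were whole multiples of the value of 1 read in each column, so whole reads were recovered, and 100% of the values came out whole within 0.001 reads. The recovered reads of the listed genes numbered 47069433, 45732612 and 47444126 in the DMSO libraries and 45319519, 40950318 and 44870229 in the B23 libraries. At this depth 1 read was worth 0.0158 to 0.0164 CPM in DMSO and 0.0197 to 0.0217 CPM in B23. The listed genes summed to 745216 to 753745 CPM in DMSO and to 890367 to 900113 CPM in B23. The divisors were not whole numbers, for example 63162121.97 in DMSO replicate 1, so the deposited CPM carry a scaling factor whose method is not given in the sources used here. All values are relative to the sequenced RNA of a library, and RNA content per cell was not measured.

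All 15496 symbols were matched to the gene names of GENCODE release 29 on GRCh38, the same assembly as hg38, which supplied positions, exon numbers, gene types and overlaps. There were 32 symbols with more than 1 gene identifier there. The authors' counting gave some overlapping genes the same reads, since 126 rows lay within 5% of an overlapping row in all 6 libraries. Beside a gene given with a value, an overlapping gene on either strand is named where its mean is at least 10% of that of the gene, because the strand setting is unknown.

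Genes with a mean of at least 1 CPM over the 6 libraries were tested, which kept 14792 and left out 704. The CPM were used as deposited, transformed to log2(CPM + 0.5), and B23 was compared with DMSO in limma 3.58.1 under R 4.3.3 with mean-variance trend and robust empirical Bayes. P-values were two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Differences are on the log2(CPM + 0.5) scale, which understates changes of low genes, while folds are ratios of mean CPM. SD is given over n = 3 libraries and SE is that of the limma fit.

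A set of 30 gene lists was fixed, with 547 entries, of which 502 were in the table. The 26 lists with at least 3 measured members were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01 and with adjustment over the 26 lists. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction and compares them with no other genes. Counts of changed members were adjusted over all tested genes, and again over the list alone.

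Genes named in the text follow a rule. They are the 8 largest rises and 8 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups; up to 3 changed members of each list with the largest change; CYR61, CTGF, ANKRD1, AMOTL2, YAP1, WWTR1 and TEAD1 to TEAD4 in every case; and the 3 genes with the smallest adjusted p in each direction. Some genes that the rule takes are not reported here. The groups, the test, the lists, the rule for named genes and all alternatives except 2 were set before the data were examined. The 2 alternatives chosen after seeing the data were a rescaling to the total of the listed genes and the removal of 71 rows that share reads with an overlapping row.

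The other alternatives were pseudocounts of 0.1 and 2, no filter or a mean of at least 5 CPM, median-of-ratios, TMM and quantile scaling, empirical Bayes without trend or robust, a replicate block, an adjusted p under 0.01, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Ranges of list medians and of adjusted p over the alternatives cover these settings and the 2 added ones, with camera at the preset correlation. The shift of the median log2 difference of all genes was computed for each scaling.

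The test was tried on simulated data for the comparison of B23 with DMSO, with 14777 genes tested and 200 changed, 50 at each fold. The glycolysis list was raised 1.5-fold in addition, and its genes count among the calls. It recovered 80% at 1.25-fold, 98% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, with 15 false calls among 220. The glycolysis list, in which changes were seeded, was called by camera with an adjusted p of 7.97e-60, and 0 of the other 25 lists were called. The simulated genes were drawn independently of each other, and few of them changed. The trial therefore does not cover lists of correlated genes, or scaling where most genes change, as in these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.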

Results

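Gene expression was measured in HEK293 cells treated with B23, a compound of the quinolinol class, and in cells given the solvent DMSO. There were 3 libraries per group, each with 40950318 to 47444126 recovered reads in the listed genes. The labels call the libraries triplicates and say nothing of separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Across genes, log2 values of replicates correlated with r of 0.998 to 0.999, while genes are not independent replicates. Reads of replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 2.67 to 6.91, so each library was counted as 1 sample. The first principal component held 98.0% of the variance.

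B23-treated cells differed from DMSO cells in most of the measured transcriptome. On the log2(CPM + 0.5) scale the largest rise was that of TNFRSF9, a receptor of the tumour necrosis factor receptor family, which went from 1.29 ± 0.0508 CPM in DMSO to 95.3 ± 0.863 CPM in B23 (SD, n = 3), 73.9-fold. The NF-κB subunit gene RELB rose 50.02-fold, from 3.21 ± 0.367 to 160.7 ± 5.07 CPM, and the chemokine gene CXCL8 rose 48.6-fold, from 0.875 ± 0.183 to 42.5 ± 0.476 CPM. On the same scale the largest fall was that of MYC, a transcription factor gene of cell growth, which was 19.7-fold lower by mean CPM, at 225.1 ± 16.4 CPM in DMSO and 11.4 ± 0.574 CPM in B23. CHAC1, which encodes a glutathione-degrading enzyme, fell from 40.9 ± 0.350 to 1.78 ± 0.402 CPM, 22.9-fold. In limma the log2 differences were 5.74 (SE 0.055, adjusted p = 8.24e-29) for TNFRSF9 and -4.24 (SE 0.047, adjusted p = 1.73e-25) for MYC. TNFRSF9 lies on chromosome 1 from 7915894 to 7943165 and MYC on chromosome 8 from 127735434 to 127741434 in GRCh38.

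Other large rises were those of MAFF (36.2-fold), the signalling adaptor gene SH2D3C (log2 difference 4.66), the NF-κB inhibitor gene TNFAIP3 (24.6-fold) and the MAP kinase phosphatase gene DUSP8 (18.9-fold). DNAH17 and SNHG12 rose 29.4-fold and 14.6-fold, and they overlap PGS1 and TRNAU1AP on the opposite strand, so part of their reads is uncertain. Large falls were those of AL139246.5 (21.6-fold), HPS6 (13.3-fold) and PPP1R10 (11.3-fold). MAT2A, the gene of a methionine adenosyltransferase, fell 11.2-fold from 520.3 ± 10.2 to 46.4 ± 4.13 CPM, DEPP1 fell 12.7-fold and SGMS1-AS1 fell 14.9-fold. These last 3 genes overlap GGCX, RASSF4 and SGMS1 on the opposite strand. Among the falls with the smallest adjusted p were SEPHS2 (8.70-fold), AL035425.3 (8.21-fold, overlapping AL035425.2) and the small GTPase gene RHOB (6.67-fold, from 957.9 ± 13.8 to 143.6 ± 4.39 CPM). HPS6, SEPHS2 and RHOB are coding genes with a single exon, a class whose median log2 difference was -1.24 over 230 genes.

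Of 14792 genes tested, 13111 (88.6%) changed, 5856 higher and 7255 lower in B23. At least 2-fold changes were called for 1428 genes higher and 2341 lower, and at least 4-fold changes on the log2 scale for 181 higher and 379 lower. The 3 B23 values did not overlap the 3 DMSO values in 13147 genes (88.9%), where chance gives 10%. The scaling of the libraries moved this balance: 55.3% of the changed genes were lower with the CPM as deposited and 67.5% when the listed genes were scaled to the same total, which shifted the median of all genes by -0.24 from -0.10. With median-of-ratios scaling 50.1% were lower. The number of genes at least 2-fold higher was 889 with listed-gene total scaling, and the number at least 2-fold lower was 1446 with quantile normalization, 1448 among genes of at least 5 CPM and 1535 with a pseudocount of 2.

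The comparison asks which transcripts differ after B23, and the labels name no pathway. Targets of TEAD factors, the DNA-binding partners of the Hippo pathway coactivators YAP and TAZ, were set as a first question from background knowledge of quinolinols, not from the sources used here. Among well-known YAP/TAZ-TEAD targets ANKRD1, AMOTL2 and CYR61 rose, while CTGF was not called. ANKRD1, a cardiac ankyrin repeat gene and a standard TEAD readout, rose 16.7-fold from 4.20 ± 0.152 to 70.3 ± 2.63 CPM (SD, n = 3). AMOTL2, which encodes an angiomotin family protein, rose 4.42-fold from 19.8 ± 0.707 to 87.6 ± 1.89 CPM, and the matricellular gene CYR61 rose 1.803-fold from 38.3 ± 1.31 to 69.0 ± 0.596 CPM. CTGF, the related matricellular gene, was at 11.3 ± 0.806 CPM in DMSO and 11.2 ± 0.660 CPM in B23, a log2 difference of -0.021 (SE 0.064, adjusted p = 0.754 in limma). The log2 differences of the others were 3.91 (SE 0.051, adjusted p = 1.69e-26) for ANKRD1, 2.12 (SE 0.040, adjusted p = 1.80e-23) for AMOTL2 and 0.84 (SE 0.038, adjusted p = 2.47e-16) for CYR61. In GRCh38 ANKRD1 lies on chromosome 10 from 90912096 to 90921276, AMOTL2 on chromosome 3 from 134355874 to 134375479, CYR61 on chromosome 1 from 85580761 to 85583962 and CTGF on chromosome 6 from 131948176 to 131951373.

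Of the 21 measured YAP/TAZ-TEAD targets, 10 rose, 10 fell and 1 did not pass the test, with the same counts adjusted over the list alone. GADD45A, a growth arrest gene also listed among p53 targets, rose 8.06-fold, and CCDC80 fell 5.11-fold from 26.7 ± 3.33 to 5.22 ± 0.417 CPM. The list was not called by camera (adjusted p = 0.798, and adjusted p = 0.938 with an estimated correlation). Fry, which compares a list with no other genes, called it (adjusted p = 3.63e-05), as it did most lists. The median log2 difference of the list was -0.021, -0.27 to 0.078 over the alternatives, its mean 0.21 and the direction of camera higher. The median, which is the value of CTGF, turned to 0.076 with median-of-ratios scaling and to 0.034 and 0.025 without DMSO replicate 1 and B23 replicate 3. CTGF itself was called higher with quantile normalization (0.34, adjusted p = 7.01e-05) and lower with listed-gene total scaling (-0.27, adjusted p = 0.00073), and its adjusted p over the alternatives ran from 7.01e-05 to 0.761.

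Genes of the Hippo pathway and of TEAD factors themselves also changed. TEAD3, TEAD4 and TEAD1 rose 2.54-fold, 2.14-fold and 1.56-fold, while TEAD2 fell 1.43-fold, from 31.6 ± 0.431 to 22.03 ± 1.54 CPM. The coactivator genes WWTR1 (TAZ) and YAP1 rose 1.94-fold and 1.43-fold, with YAP1 at 65.4 ± 1.68 CPM in DMSO and 93.5 ± 1.67 CPM in B23. AMOT, the angiomotin gene, fell 3.61-fold from 233.1 ± 10.5 to 64.5 ± 1.68 CPM. Of 25 members 14 rose, 8 fell and 3 did not pass the test, in the same numbers adjusted over the list alone, and the list was not called (median 0.24, -0.016 to 0.34 over the alternatives, camera adjusted p = 0.190). Its median turned to -0.016 with listed-gene total scaling.

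**Figure D1:**
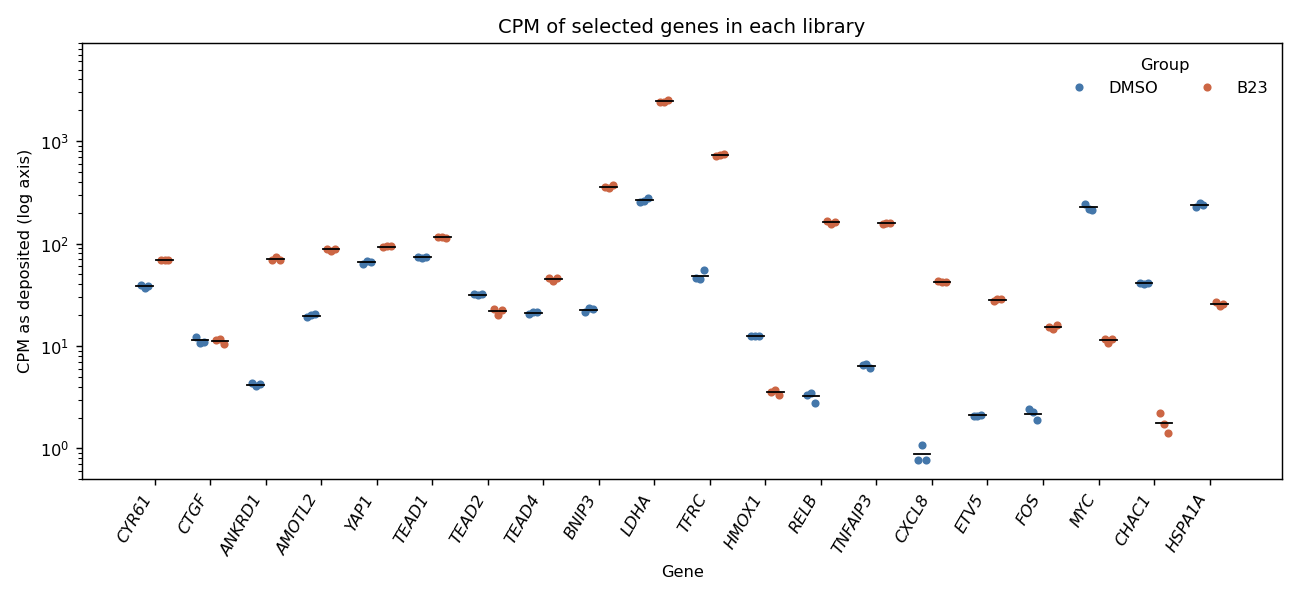
CPM per library on a log axis for 20 genes in the 3 DMSO and 3 B23 libraries, with points for libraries and lines for group means. ANKRD1 stands near 4.20 CPM in DMSO and 70.3 CPM in B23, MYC falls from 225.1 to 11.4 CPM, and the CTGF points of both groups lie around 11.3 and 11.2 CPM.

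Genes of glycolysis and of the hypoxia response rose together. Of 17 glycolysis enzymes 16 rose, 0 fell and 1 did not pass the test, at the limma threshold and adjusted over the list alone, with a median log2 difference of 1.87. LDHA, the lactate dehydrogenase A gene, rose 9.24-fold from 264.1 ± 14.1 to 2439.9 ± 64.9 CPM, ALDOC rose 7.98-fold and the hexokinase gene HK2 rose 6.53-fold. Of 25 hypoxia and HIF target genes 22 rose and 3 fell (median 1.41), with the same counts adjusted over the list alone. BNIP3, a mitophagy receptor gene, rose 15.9-fold from 22.6 ± 1.12 to 360.0 ± 9.75 CPM, PDK1, a kinase gene that restrains pyruvate oxidation, rose 9.46-fold and the collagen prolyl hydroxylase gene P4HA1 rose 8.78-fold. The 3 that fell, chosen after their values were seen, were EGLN3, DDIT4 and CA12. Camera called both lists with an adjusted p of 4.61e-06, with an adjusted p = 0.484 with an estimated correlation for glycolysis and an adjusted p = 0.330 with an estimated correlation for hypoxia.

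NF-κB and inflammatory genes had a median of 2.82, the highest of the lists with the filter at 1 CPM, and 8 of 10 measured members rose while 2 fell, also adjusted over the list alone. Without the filter, which adds members with a mean under 1 CPM, the median was 1.30, below those of glycolysis and hypoxia, and the list was still called. RELB, CXCL8 and TNFAIP3, given above, had the largest rises of the list, and TRAF1 and TNFAIP2, chosen after their values were seen, were the members that fell. The camera adjusted p was 0.00461 (adjusted p = 0.330 with an estimated correlation). Among MAPK pathway activity genes 9 of 13 rose, 3 fell and 1 did not pass the test, with the same counts adjusted over the list alone (median 1.01). The ETS factor gene ETV5 rose 13.4-fold from 2.10 ± 0.0285 to 28.2 ± 0.735 CPM, the feedback inhibitor gene SPRY4 rose 9.14-fold, and ETV4, which overlaps DHX8 on the opposite strand, rose 6.85-fold. The 3 that fell, chosen after their values were seen, were CCND1, PHLDA1 and EPHA4. The MAPK list was called with a camera adjusted p of 0.0326 (adjusted p = 0.330 with an estimated correlation), and the call was lost among genes of at least 5 CPM (adjusted p = 0.0932, in a range of 0.00563 to 0.0932 over the alternatives).

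Cell cycle genes were higher on balance in B23. Of 22 G1/S genes 20 rose and 2 fell (median 0.80, 0.35 to 0.90 over the alternatives), among them E2F1 (3.70-fold), the replication helicase gene MCM7 (3.55-fold, from 384.0 ± 8.87 to 1361 ± 40.2 CPM) and CDC6 (3.19-fold). Of 22 G2/M genes 14 rose, 5 fell and 3 did not pass the test (median 0.43, 0.13 to 0.53 over the alternatives). The spindle genes TPX2 and KIF11 rose 2.82-fold and 2.59-fold, and NUSAP1, which overlaps AC087721.2, rose 3.64-fold. Members that fell, named after their values were seen, were CCNE1 and FEN1 for G1/S and CENPE, PLK1, CENPF, CCNB1 and KIF20A for G2/M. Both counts were the same adjusted over the list alone. Camera gave an adjusted p of 7.64e-05 for G1/S (adjusted p = 0.484 with an estimated correlation) and of 0.0395 for G2/M (adjusted p = 0.851 with an estimated correlation). The G2/M call was lost without DMSO replicate 1 (adjusted p = 0.0565), with the filter at 5 CPM (0.0932) and with quantile normalization (0.475), in a range of 0.00295 to 0.475.

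Of 22 cholesterol synthesis genes 17 rose, 3 fell and 2 did not pass the test (median 0.74, 0.49 to 0.85 over the alternatives). The mevalonate pathway genes IDI1 and HMGCS1 rose 3.70-fold and 3.60-fold, with HMGCS1 at 59.3 ± 2.53 CPM in DMSO and 213.6 ± 11.4 CPM in B23. Of 18 genes of histone demethylases and related 2-oxoglutarate dioxygenases, enzymes that need iron and oxygen, 14 rose, 2 fell and 2 did not pass the test (median 0.77). KDM3A, which is also on the hypoxia list, rose 6.77-fold, KDM6B rose 4.70-fold and KDM4B rose 3.58-fold. Among the members that fell were NSDHL and PMVK of the first list and KDM4A and KDM2B of the second, named after their values were seen. Camera gave each of these lists an adjusted p of 0.00114, with an adjusted p = 0.440 with an estimated correlation for cholesterol synthesis and an adjusted p = 0.330 with an estimated correlation for the dioxygenases. Of 28 nuclear-encoded oxidative phosphorylation genes 20 rose, 7 fell and 1 did not pass the test (median 0.34, 0.021 to 0.44 over the alternatives), including SDHA (2.28-fold), UQCRC1 (2.36-fold) and NDUFA9 (2.38-fold, overlapping AC005832.4 and AC005833.1). This list was called at an adjusted p of 0.0395 (adjusted p = 0.851 with an estimated correlation), and the call was lost in edgeR (0.0716), in DESeq2 (0.0574), at 5 CPM (0.0932) and with quantile normalization (0.907), in a range of 0.0254 to 0.907. The counts of the 3 lists were the same adjusted over the list alone.

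These 9 lists, all higher in B23, were the ones called among 26. The lists were not matched to other genes on exon number, with which the medians of coding genes rose, as given below. With an estimated correlation camera called 0 lists at an adjusted p under 0.05 and 2 at an unadjusted p under 0.05, and fry gave 25 lists a directional adjusted p under 0.05. Among the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05, the real split called 9 lists and the highest other split 8. Each other split keeps part of the treatment contrast, because its sides mix both treatments unevenly, so these counts cannot test chance.

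Iron handling genes went both ways. TFRC, the transferrin receptor gene, rose 15.1-fold from 48.5 ± 5.44 to 731.6 ± 13.8 CPM (log2 difference 3.91, SE 0.065, limma adjusted p = 5.50e-13), while the ferrireductase gene STEAP3 fell 3.63-fold and the heme oxygenase gene HMOX1 fell 3.55-fold. Of 14 members 8 rose, 5 fell and 1 did not pass the test (median 0.11, -0.18 to 0.22 over the alternatives, mean -0.073, camera adjusted p = 0.855), and the median turned to -0.18 with quantile normalization and to -0.14 with listed-gene total scaling. Metallothionein and zinc transporter genes had 0 of 9 members higher and 7 lower, with 2 not passing the limma test (median -0.19, -0.50 to -0.099 over the alternatives, camera adjusted p = 0.137). SLC39A10 fell 2.89-fold, SLC30A10 fell 3.62-fold and MT1X, which overlaps AC026461.1, fell 2.65-fold.

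Stress response genes were mixed as well, and none of their lists was called. Of 16 NRF2 antioxidant genes 5 rose, 6 fell and 5 did not pass the test, with 5 higher and 5 lower adjusted over the list alone. SLC7A11, the cystine transporter gene, fell 2.37-fold, and OSGIN1, which overlaps AC009119.2, rose 5.06-fold. The median of -0.0010, -0.25 to 0.10 over the alternatives, turned to 0.10 with median-of-ratios scaling, and camera, with the direction higher, gave an adjusted p of 0.981. Of 23 ATF4 and amino acid response genes 9 rose, 13 fell and 1 did not pass the test (median -0.46, -0.72 to -0.36 over the alternatives, camera adjusted p = 0.772), with ATF3 5.19-fold higher and the single-exon gene CEBPB 3.71-fold lower. The ATF4 list was called lower with quantile normalization (adjusted p = 0.0300, in a range of 0.0300 to 0.860). Of 17 endoplasmic reticulum chaperone genes 5 rose, 11 fell and 1 did not pass the test (median -0.31, -0.56 to -0.21 over the alternatives, camera adjusted p = 0.4997). SDF2L1 fell 2.98-fold, PDIA4 fell 1.81-fold and CRELD2, which overlaps ALG12 on the opposite strand, fell 1.70-fold. This list was also called with quantile normalization (adjusted p = 0.0409, in a range of 0.0409 to 0.593).

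Of 15 cytosolic heat shock genes 6 rose and 9 fell (median -0.33, -0.62 to -0.23 over the alternatives, camera adjusted p = 0.785). HSPA1A fell 9.25-fold from 237.0 ± 11.1 to 25.6 ± 1.246 CPM and the single-exon gene HSPA1B fell 6.19-fold. HSPA1B overlaps AL671762.1, and because the sequences of HSPA1A and HSPA1B are nearly identical, the assignment of reads between them is uncertain and was not tested. The cochaperone gene CHORDC1 rose 4.56-fold. Of 22 p53 targets 11 rose, 9 fell and 2 did not pass the test (median 0.13, -0.12 to 0.23 over the alternatives, camera adjusted p = 0.4997), including AEN (2.55-fold higher) and BBC3 (2.51-fold higher), and the median turned to -0.0084 with quantile normalization and to -0.12 with listed-gene total scaling. Of 13 interferon-stimulated genes 5 rose, 5 fell and 3 did not pass the test. IFIT1 fell 22.6-fold from 6.16 ± 0.244 to 0.272 ± 0.0597 CPM, IFIT2, which overlaps LIPA on the opposite strand, fell 7.52-fold, and ISG15 rose 4.46-fold. The interferon median was -0.17, -0.39 to 1.46 over the alternatives, and camera's direction was higher (adjusted p = 0.996). Among the 5 members of at least 5 CPM the median was 1.46 and the list was called higher (adjusted p = 0.0291, in a range of 0.0291 to 0.999), and the median was 0.36 with quantile normalization.

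Of 21 immediate early and AP-1 genes 14 rose, 6 fell and 1 did not pass the test (median 0.79, camera adjusted p = 0.0704). FOS rose 6.96-fold and ZFP36 rose 5.85-fold, in contrast to MYC, and edgeR and listed-gene total scaling called the list higher (adjusted p = 0.0397 and 0.0135, in a range of 0.0135 to 0.124). Of 16 SRF and actin cytoskeleton targets 10 rose, 5 fell and 1 did not pass the test (median 0.37, 0.13 to 0.48 over the alternatives, camera adjusted p = 0.137), with the focal adhesion gene ZYX 5.30-fold, the tropomyosin gene TPM4 2.68-fold and FHL2 2.50-fold higher. EdgeR and DESeq2 called this list higher (adjusted p = 0.0397 and 0.0259, in a range of 0.0259 to 0.205). Of 15 TGF-β response genes 6 rose, 8 fell and 1 did not pass the test (median -0.18, -0.43 to -0.082 over the alternatives, camera adjusted p = 0.772). ID2 fell 6.11-fold from 299.7 ± 4.65 to 49.1 ± 2.07 CPM, TGFBI rose 6.68-fold and BHLHE40 rose 3.35-fold.

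Of 37 cytosolic ribosomal protein genes 8 rose, 17 fell and 12 did not pass the test. RPL7A fell 1.48-fold, and RPLP2, which overlaps PIDD1 on the opposite strand, fell 1.36-fold. The median was -0.07, -0.43 to 0.030 over the alternatives (camera adjusted p = 0.733), turned to 0.030 with median-of-ratios scaling and was called lower with quantile normalization (adjusted p = 0.000156, in a range of 0.000156 to 0.978). Of 13 mitochondrially encoded mRNAs 6 rose and 7 fell (median -0.26, -0.60 to -0.15 over the alternatives, camera direction higher, adjusted p = 0.996), against 1 and 8 with quantile normalization and 2 and 7 with listed-gene total scaling. MT-CO2 rose 1.96-fold, MT-ND6 fell 10.7-fold from 18.4 ± 1.72 to 1.72 ± 0.401 CPM, and MT-CYB rose 1.62-fold (limma adjusted p = 6.29e-05) but was not called with quantile normalization (adjusted p = 0.111, in a range of 8.54e-14 to 0.111).

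Markers of other cell types gave no uniform shift. Of 8 neuronal lineage markers 5 rose and 3 fell (median 0.70, 0.34 to 0.92 over the alternatives, camera adjusted p = 0.419), with TUBB3, which overlaps AC092143.1, 4.19-fold, MAP2 2.46-fold and SYP 2.09-fold higher. Of 7 epithelial markers 4 rose and 3 fell (median 0.27, 0.018 to 0.94 over the alternatives, camera adjusted p = 0.721). KRT8, which overlaps KRT18 on the opposite strand, rose 2.77-fold, while the cadherin gene CDH1 fell 3.07-fold and CLDN7, which overlaps AC003688.1 and ELP5, fell 2.81-fold. The remaining lists had fewer than 3 measured members and were not tested. PDGFRA, which overlaps AC058822.1, fell 3.69-fold and COL1A1 rose 1.32-fold among 2 fibroblast markers. ESAM rose 1.47-fold as the only endothelial marker measured, and CD68, which overlaps AC016876.1 and AC016876.2, rose 1.76-fold as the only blood cell marker. Of the non-polyadenylated RNAs RN7SK, which holds the same reads as the overlapping RF00100, alone was measured, at 3.37 ± 1.23 CPM in DMSO and 1.97 ± 0.333 CPM in B23 (log2 difference -0.61, limma adjusted p = 0.0262), and its call was lost without DMSO replicate 1 (0.0558) and without B23 replicate 1 (0.0671), in a range of 1.87e-05 to 0.759. For the lists of these last 5 paragraphs, NRF2 excepted, counts were the same adjusted over the list alone.

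**Figure D2:**
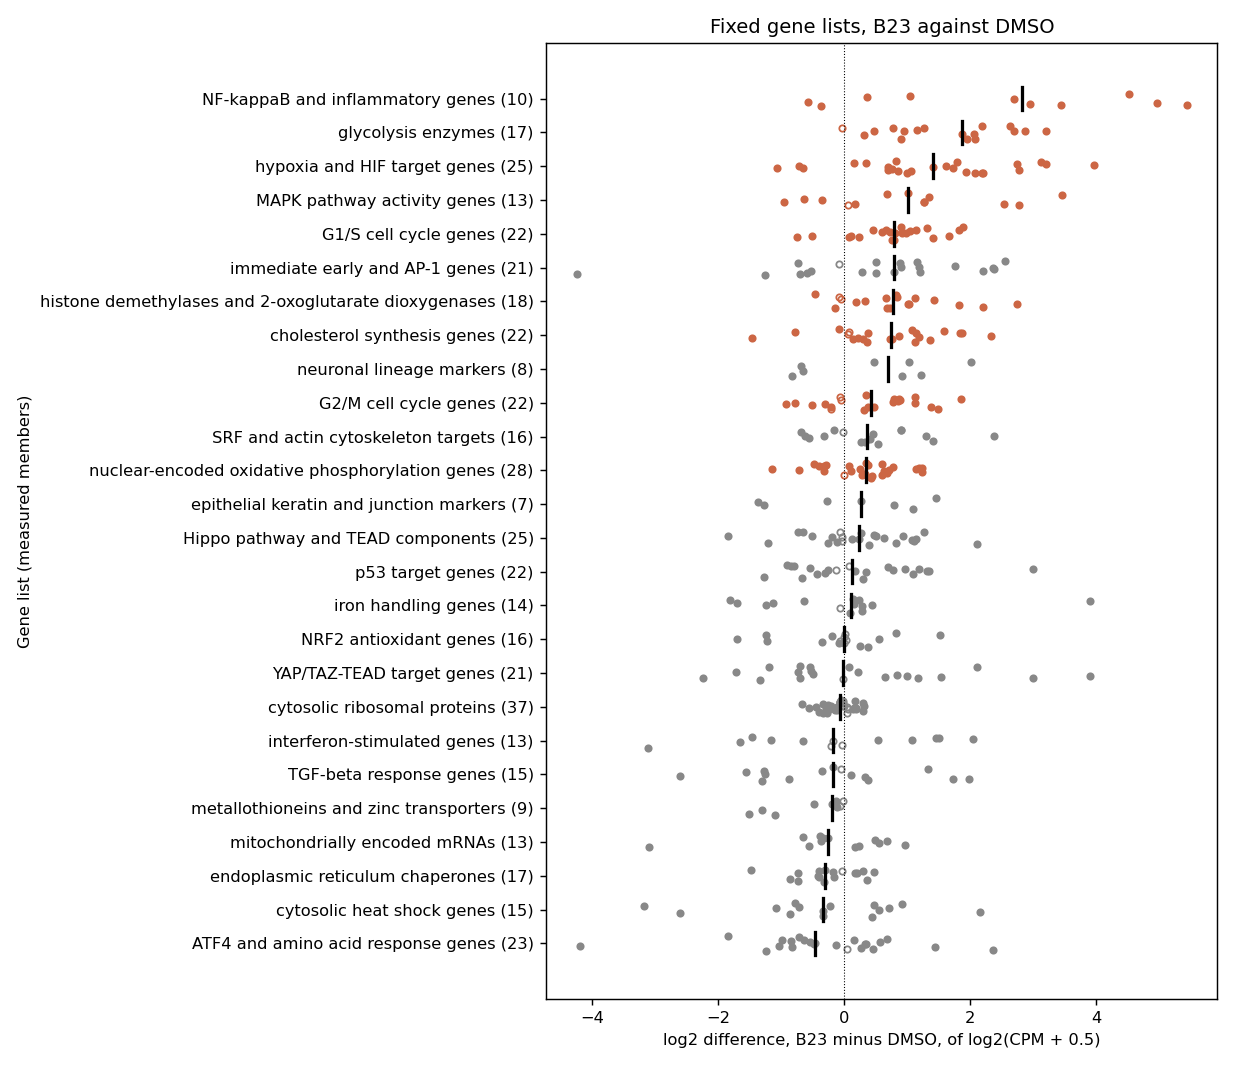
Log2 difference of B23 minus DMSO for each measured member of each fixed list, sorted by list median (black bar), with called lists in orange, others in grey, and filled points for members with an adjusted p under 0.05. With the CPM as deposited and the filter at 1 CPM the NF-κB median is 2.82, the glycolysis median 1.87 and the hypoxia median 1.41, and without the filter the NF-κB median is 1.30.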

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

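The rescaling to the total of the listed genes, the removal of rows that share reads, and the count of changed genes over other splits of the libraries were chosen after the data were seen. The number of changed genes stayed between 10794 (mean of at least 5 CPM, with fewer genes tested) and 13402 (listed-gene total scaling), with 12904 to 13036 when 1 library was left out. Quantile normalization called 698 and listed-gene total scaling 362 of the 13111 changed genes in the opposite direction, and no other alternative called any so. EdgeR on the recovered reads called 6358 genes higher and 6797 lower, and DESeq2 6424 and 6453. At least 2-fold rises numbered 889 with listed-gene total scaling. At least 2-fold falls numbered 1535 with a pseudocount of 2, 1448 at 5 CPM (fewer genes tested) and 1446 with quantile normalization. Called lists numbered 0 with an estimated correlation and 25 with fry, which asks another question. The YAP/TAZ-TEAD median and CTGF, which is the median gene, turned to 0.076 with median-of-ratios scaling, 0.050 with TMM, 0.048 in edgeR and 0.078 in DESeq2, and ran from -0.057 to 0.034 when 1 library was left out (0.034 without DMSO replicate 1, 0.025 without B23 replicate 3). CTGF was 0.34 with quantile normalization. Fry called the YAP/TAZ-TEAD list (adjusted p = 3.63e-05), whose median was -0.021 and whose mean was 0.21, so the median does not give the direction of that call. The NRF2 median was 0.10 with median-of-ratios scaling and in DESeq2 and 0.074 and 0.073 with TMM and edgeR. The ribosomal protein median was 0.030 with median-of-ratios scaling and in DESeq2, 0.0035 with TMM and 0.00057 in edgeR. With quantile normalization the iron, p53 and interferon medians were -0.18, -0.0084 and 0.36, and with listed-gene total scaling the iron, p53 and Hippo medians were -0.14, -0.12 and -0.016. The interferon median was 1.46 at 5 CPM, where 5 members remained. Median-of-ratios, TMM and listed-gene total scaling shifted the median of all genes by 0.098, 0.073 and -0.24. List medians moved by similar amounts under these scalings, as a rescaling moves all genes of a library alike. By construction the filters change the number of genes, and a larger pseudocount shrinks the differences of low genes. For the other settings the cause was not tested. Replicate numbers gave no sign of pairing the libraries: same-numbered deviations correlated at 0.026, -0.070 and -0.062, and no DMSO library correlated best with its own number. With 3 libraries per group, whose deviations from the group mean depend on each other, these correlations cannot exclude a pairing. A replicate block gave 13106 changed genes, 5850 higher and 7256 lower, of which 13071 were called before in the same direction. Of the named genes' values under alternatives, 1931 kept direction and call, 6 lost the call (RN7SK and MT-CYB), 1 gained it and 7 turned (CTGF). Of the 10 splits of the 6 libraries, too few for a share under 0.05, only 1, the real one, gave as many as 13111 changed genes, and the highest other gave 0 in limma (1 at an unadjusted p under 0.05). For called lists likewise only 1 split, the real one, reached 9, and the highest other gave 8, while at an unadjusted p under 0.05 the real split gave 10 lists and the highest other 12. The other splits mix both treatments on each side, which keeps part of the contrast and adds the rest to the spread. Neither the gene counts nor the list counts of the splits can therefore test chance.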

Other observations

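Of the tests in this part, those on other non-coding RNAs and on non-polyadenylated RNA were chosen only after their results were seen. Host genes of small nucleolar RNAs, long non-coding RNAs whose introns hold those RNAs, were mostly higher in B23, a set chosen after their values were seen. Of 19 measured host genes 13 rose and 6 fell, with a median log2 difference of 0.73, against -0.67 over 962 other non-coding rows. SNHG17 rose 8.21-fold from 37.9 ± 1.81 to 310.9 ± 9.02 CPM (SD, n = 3), SNHG15 rose 4.21-fold, SNHG1 rose 2.33-fold and GAS5 rose 1.66-fold, while SNHG3, which overlaps RCC1, went from 98.8 ± 5.67 to 45.2 ± 2.04 CPM and SNHG4, which overlaps MATR3 and SIL1, from 61.7 ± 2.09 to 18.9 ± 0.858 CPM. Of 14 genes of SR splicing factors and their TRA2 relatives 10 rose and 4 fell (median 0.83). SRSF7 rose 4.10-fold from 199.5 ± 9.15 to 817.9 ± 9.96 CPM and SRSF11 rose 3.49-fold, while SRSF8 fell from 64.7 ± 2.99 to 12.4 ± 0.824 CPM, and SRSF1 (overlapping AC015813.2), SRSF5 and SRSF12 also fell. With listed-gene total scaling and with quantile normalization 11 host genes rose and 7 fell, and the host and SR medians stayed above 0 under each scaling tried but went down to 0.48 and 0.37 with quantile normalization.

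Mitochondrial transcripts went both ways. MT-RNR2, the 16S ribosomal RNA, rose 6.72-fold from 477.5 ± 38.0 to 3209 ± 97.4 CPM and MT-RNR1, the 12S ribosomal RNA, rose 3.04-fold from 127.5 ± 4.89 to 387.2 ± 10.6 CPM, both also under each scaling tried. Among mitochondrial mRNAs MT-ND6 fell 10.7-fold, as given above, MT-ND2 was at 2076 ± 169 CPM in DMSO and 1322 ± 140 CPM in B23 and MT-ND4, which overlaps MT-ND4L, at 1694 ± 94.99 and 2396 ± 317 CPM. Of 7 measured mitochondrial tRNAs 6 fell and 1 rose, the latter being MT-TL1, which did not rise with listed-gene total scaling, and 5 fell with quantile normalization. The tRNA median log2 difference was -1.98. MT-TM, the most abundant of them, went from 164.7 ± 7.94 to 95.4 ± 2.11 CPM. MT-TK went from 4.31 to 0.127 CPM, MT-TP from 2.92 to 0.0633, MT-TE from 2.44 to 0.118 and MT-TV from 2.13 to 0.164, with the B23 values worth only a few reads. A poly(A) library samples ribosomal RNA and tRNA poorly, so these values compare captured RNA.

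Coding genes with a single exon were lower in B23 than other coding genes: 198 of 230 (86.1%) fell and 20 rose, with a median log2 difference of -1.24 against -0.06 over 12963 genes with several exons, a difference of -1.18 (95% bootstrap interval -1.32 to -1.06, camera p = 3.81e-14, and p = 0.0114 with an estimated correlation). This class was not among the fixed lists, so the interval and the p-values describe a pattern of these data and are not a preset test. Medians rose with exon number, from -0.88 at 2 exons and -0.34 at 4 to 5 exons to 0.15 above 20 exons. The tables argue against GC content, since the difference within GC bins was -1.13 (-1.29 to -0.94), and against transcript length, with -1.12 (-1.32 to -0.96) within length bins. Genomic DNA in the DMSO libraries is argued against as well, because the median DMSO excess of the fallen single-exon genes was 11.2 times the level per kilobase of the lowest genes with several exons. The difference was -0.87 (-1.08 to -0.73) within expression bins and -0.96 with quantile normalization, and what gives rise to it stays open, since an effect of the treatment on intronless or unstable transcripts was not tested.

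A rise of non-coding RNAs in general is argued against for the host genes, since the median of the other non-coding rows was -0.67 (95% bootstrap interval -0.74 to -0.58), which the host median exceeded by 1.40. With quantile normalization that median was -0.16, with 347 rows higher and 464 lower, and the host median exceeded it by 0.64. The exon-number trend did not account for the whole host difference. Other non-coding rows with the exon numbers of the host genes had a weighted median of -0.52, and the difference within exon-number bins was 0.93 (95% interval 0.40 to 1.89). The host genes were chosen after their values were seen, and the comparison with other non-coding rows after its result. These differences therefore describe a pattern of these data and are not a preset test. A candidate explanation is slower nonsense-mediated decay, which clears many host gene transcripts and the poison-exon forms of SR genes, and the prediction that SRSF and TRA2 genes stand above other coding genes with several exons was met, with a difference of 0.89 (permutation p = 0.0006), of 0.40 with quantile normalization and of 0.84 (0.40 to 1.24) within exon-number bins. The permutation and the intervals were taken over genes, treated as independent, and do not measure the spread between libraries. Slower decay remains a hypothesis, as higher transcription of these genes was not tested and ATF4 targets, another class that decay can restrain, had a median of -0.46.

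For the rise of MT-RNR2, more carry-over of non-polyadenylated RNA into the B23 libraries could be the source. The median log2 difference of 53 other rows of gene types taken as non-polyadenylated, with mitochondrial tRNAs left out, was 0.45 (95% interval -0.08 to 0.65). Many of these rows are short annotated stretches inside long non-coding RNAs such as NEAT1, TUG1, HOTAIRM1 and ZFAS1. RF02216 and RF02217, which overlap ZFAS1, stood at 1.81 and 1.97, against 1.92 for ZFAS1. The median therefore does not measure non-polyadenylated RNA alone. Carry-over cannot be told apart from an effect of the treatment, because 52 of the 53 overlap another row on either strand and may share its reads. RN7SK and RF00100, which hold the same reads, are both counted. RN7SK and 6 of 7 mitochondrial tRNAs fell (tRNA median -1.98), which a uniform carry-over would not give. However, RN7SK lost its call in some alternatives, and several of the tRNAs were worth only a few reads in B23. MT-TM lies beside MT-ND2, so its reads may be those of a shared precursor. MT-RNR1, the only one of the 53 rows without an overlap, rose 3.04-fold.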
